A study of Homo sapiens with 24 samples.

How the data were processed

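RNA from D425 cells was hybridised to Affymetrix U133 Plus 2.0 arrays, 1 array per sample, per the labels' protocols. The labels give 18 arrays of cells with an inducible hairpin against OTX2, in 3 independent time courses, and 6 arrays of 1 control course. Each course covers 0, 8, 16, 24, 48 and 96 h after doxycycline. The groups, the time points and the course numbers were taken from the labels, which gave 12 groups. No array was left out.

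The deposited values are MAS5 signal intensity on a linear scale. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 intensity, and per the submitters' processing notes MAS5 and GCOS were used, with versions not given in the sources used here. The deposited intensity had a trimmed mean between 100.011 and 100.014 on every array when 2% was trimmed at each end, so each array had been scaled as a whole to a target of 100. No other step between arrays was seen, and the deposited table has no detection calls. Such scaling fixes each array's total, so a shift shared by most genes would not be visible. The values ran from 0 to 15458, none was missing, and at most 1.2% of probe sets had equal values in any pair of arrays, so no array was a copy of another. Array data have no read depth, and the number of arrays limits the precision.

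Probe sets were named from the platform annotation, which listed 42898 of the 54675 probe sets. Of these, 41091 had 1 gene symbol and 1801 had several, and 11777 were not in the table and stay unnamed here. Symbols were updated by Entrez ID for 41037 probe sets with the RefSeq gene table of GRCh38.p14, and no coordinates were taken from it. The 62 control probe sets whose names start with AFFX were left out of the tests. A probe set was kept when its signal exceeded the array median in at least 3 arrays, which 33803 did. Each gene was represented by its kept probe set with the highest mean, which gave 13903 genes, of which 7014 had more than 1 kept probe set. In 7 of the 124 named genes the kept probe sets differed in sign at 96 h, namely BTG3, COL1A1, COL4A4, EBP, NRL, OTX2 and POLR1B.

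Signals were transformed as log2(signal + 16), so log2 changes are on that scale and understate the change of dim genes. All tests used limma 3.58.1 in R 4.3.3, with lmFit on the 12 group means of all 24 arrays and eBayes with a mean-variance trend. A gene is called when its Benjamini-Hochberg adjusted p over all tested genes is under 0.05. The spread comes from the shOTX2 groups alone, with 12 residual degrees of freedom. The control groups hold 1 array each and are assumed to vary like the shOTX2 groups. The comparisons were each shOTX2 time against 0 h, late (48 and 96 h) against early (0 and 8 h) in each arm, the difference of these changes between the arms, the same difference for 96 h against 0 h, and the arms at 0 h.

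The time course number pairs arrays across times, since the labels describe independent courses. Deviations from the group means correlated between same-numbered arrays in all 45 pairs of different times (r across genes from 0.154 to 0.553, median 0.242), and 16 of 18 arrays correlated best with an array of their own course. The median was 0.500 within course 1, 0.231 within course 2 and 0.196 within course 3. Between courses 2 and 3 it was 0.164 (highest 0.262), and between course 1 and these -0.325 and -0.303. The pattern thus parts course 1 from the other courses more than course 2 from course 3. A fit with the course as a replicate block has 10 residual degrees of freedom, holds the control course as its own block and so cannot compare the arms at 0 h. It is given beside a named gene whose call it changes, a count of genes that it moves by over 1.5 times, and the counts of lists from 8 to 48 h.

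The 21 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list. limma's fry was run as another set test. The lists hold 725 different genes, of which 685 had a named probe set and 563 were tested. They cover OTX family and anterior hindbrain patterning factors, photoreceptor and visual transduction, G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors and exit, MYC and ribosome biogenesis, neuronal differentiation, neural progenitor, axon guidance, medulloblastoma group 3 and group 4 markers, medulloblastoma WNT and SHH markers, WNT pathway, p53 targets, interferon response, integrated stress response and ATF4 targets, unfolded protein response, hypoxia and glycolysis, cholesterol biosynthesis, astrocyte and oligodendrocyte markers, mesenchymal and fibroblast markers, and immune and endothelial markers.

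The groups, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined. The rule names OTX2. It names the 12 largest rises and 12 largest falls at 96 h among genes called with the same sign in all 3 courses, 5 each way at 24 h and up to 3 each way at 8 and 16 h. It names the 6 largest rises and 6 largest falls against control among genes called the same way late against early in shOTX2, and up to 4 called genes each way in the control course and at 0 h. Per list it names up to 4 called members with the largest change at 96 h, or 2 as values where none was called. A fixed set of further genes is given whether called or not. It holds CRX, NRL, MYC, CCND1, CCND2 and CDKN1B, and 1 more gene of that set is not analysed here.

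The fit was tested on simulated arrays built from the real gene means, course offsets and residual spread, with 200 of 13903 genes changed. For 96 h against 0 h it recovered 19.4% of changes of 0.5 log2, 65.7% of changes of 1 and 95.5% of changes of 2, with 1 false call. For the control arm's late against early comparison the shares were 11.9%, 52.2% and 93.9%, and for the late against early difference between the arms 4.48%, 35.8% and 89.4%. Over the 5 comparisons tried the fit without the block made 0 to 1 false calls, and the fit with it recovered more changes with 6 to 13 false calls. A list of 52 genes shifted by -0.5 at 96 h was called, and 0 of the other 20 lists were. The simulated noise was independent between genes, so this does not test false list calls that correlated genes can give. The alternatives were other pseudocounts (1 and 64), quantile normalization, median centring, no filter or a stricter filter, other choices of probe set, other variance models, the replicate block, fits of only the groups compared, other time windows, other set tests, and leaving out each shOTX2 course or control array in turn. Figures were drawn with matplotlib 3.10.9.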

Results

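Gene expression was profiled in D425, an established human medulloblastoma cell line, after doxycycline switched on a short hairpin RNA against OTX2. OTX2 encodes a homeobox transcription factor of the developing brain. The question was how the transcriptome changes over time once the hairpin is induced, and the title of the series names cell cycle genes and differentiation. There were 24 arrays: 3 per time point in the arm labelled shOTX2 and 1 per time point in the control course, at 0, 8, 16, 24, 48 and 96 h. The median signal per array lay between 16.3 and 20.6 and the highest signal between 9285 and 15458, and the number of arrays limits the precision. Of 54675 probe sets, 33803 passed the filter and represented 13903 tested genes.

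The first principal component held 49.6% of the variance and the second 12.5%. On the second, course 1 and the control course lay between -28.6 and -4.49, and courses 2 and 3 between 6.998 and 30.9. The actin 3'/5' probe ratio, a sign of RNA or labelling quality, divided them the same way: 1.42 ± 0.0836 (SD, n = 6) in course 1 and 1.40 ± 0.0858 in the control, against 2.07 ± 0.198 in course 2 and 1.91 ± 0.0572 in course 3. The GAPDH ratio averaged between 1.06 and 1.08 in all courses.

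The targeted gene was examined first. OTX2 was among the brighter genes of these cells, with 106 genes brighter on average. On its brighter probe set the signal was 4659 ± 217 (SD, n = 3) at 0 h, 4112 ± 187 at 8 h, 4052 ± 253 at 24 h and 4188 ± 302 at 96 h, which is 89.9% of the 0 h mean. All 15 induced shOTX2 arrays lay below the 0 h array of their own course, and on the second probe set 9 of 15 did. The change at 96 h was -0.15 on the log2 scale (SE 0.088) and was not called by limma (adjusted p = 0.172), but it was called with the course as a block (adjusted p = 0.0331) and with each array centred on its median (-0.30, adjusted p = 0.00977). Over all alternatives the adjusted p ran from 0.00977 to 0.898. The 24 h change of -0.20 had an adjusted p of 0.224, and of 0.0247 with the block. The second probe set read 3027 ± 155 at 0 h, 2437 ± 22.2 at 8 h and 3295 ± 275 at 96 h, and none of its changes was called, with a log2 change of 0.12 and an adjusted p of 0.353 at 96 h. The control course went from 4964 to 5357 on the brighter probe set and from 3308 to 3882 on the other. Against the control's own change, the 96 h value was -0.26 (adjusted p = 0.384). Where the hairpin and the probes lie on the transcript is not given, so the probe sets may read a part that silencing leaves and do not check the labels. The arrays are therefore called by their labels throughout.

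**Figure D1:**
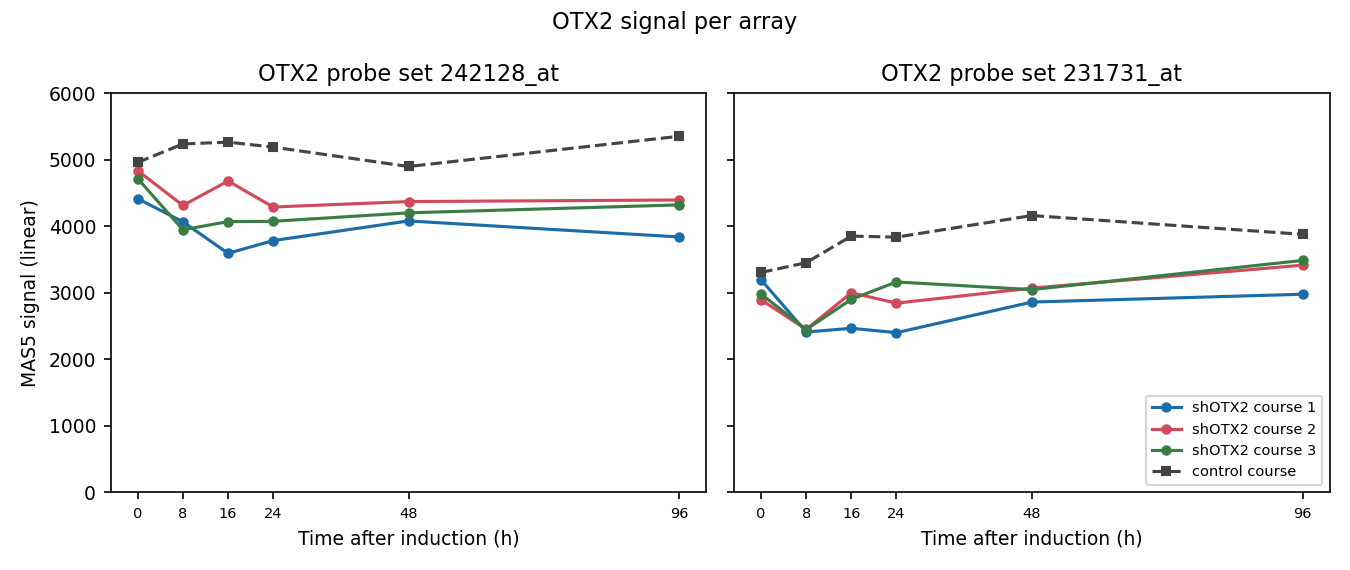
OTX2 signal (linear MAS5 signal, vertical axis) on each array against hours after induction, for both OTX2 probe sets. Each line is 1 course, solid circles for the shOTX2 courses and dashed squares for the control; on the brighter probe set the shOTX2 mean is 4659 at 0 h and 4188 at 96 h.

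By 96 h the arrays labelled shOTX2 had gained transcripts typical of neurons. CNTN2, an axonal cell adhesion molecule, rose from 7.87 ± 8.71 (SD, n = 3) to 2125 ± 215, a log2 change of 6.54 (SE 0.32, adjusted p = 9.05e-11). GRIA2, an AMPA receptor subunit, rose from 3.17 ± 0.757 to 1579 ± 317, and DCX, a microtubule-associated protein of migrating neurons, from 15.8 ± 13.4 to 1374 ± 456. STMN2, a stathmin of growing axons, rose by 4.99 on the log2 scale. The other genes among the 12 largest rises were the amino acid transporter gene SLC7A7 (5.78), PPP1R17 (5.77), the somatostatin receptor gene SSTR2 (5.62), NEB (5.54), ITGA7 (5.49), FNDC5 (5.18), C11orf96 (5.16) and LRRC10B (5.14). In the control course CNTN2 read 9.10 at 0 h and 43.6 at 96 h, and DCX 15.7 and 51.5. The largest fall was that of CTSV, a lysosomal cysteine protease, from 2069.9 ± 360.2 to 75.1 ± 23.4, with a log2 change of -4.54 (SE 0.24, adjusted p = 1.61e-10). TIMP3, a metalloproteinase inhibitor, fell from 1025 ± 540.4 to 36.3 ± 9.56, and CA2, a carbonic anhydrase, from 489 ± 121 to 11 ± 1.82. ERC2, a protein of the presynaptic active zone, changed by -4.13, the basement membrane collagens COL4A3 and COL4A4 by -3.86 and -3.17, and the water channel AQP1 by -3.71. The remaining large falls were those of TTC12 (-3.49), ADAM28 (-3.49), ARSI (-3.39), HKDC1 (-3.29) and ADAMTS8 (-3.28). The kept probe sets of COL4A4 differed in sign.

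In all, limma called 6058 of 13903 genes at 96 h against 0 h (43.6%), 2932 higher and 3126 lower, and 2212 of them changed at least 2-fold. The sign was the same in all 3 courses for 6031 of the 6058, which were chosen by the mean of those courses. Centring each array on its median moved the median of all genes by -0.15 and the split to 2243 higher and 4020 lower (35.8% higher, against 48.4%), so the balance of rises and falls rests on the scaling.

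Cell cycle genes fell almost as a whole at 96 h. Of 62 genes of G2/M and mitosis, 61 fell and 0 rose, and as many were called adjusted over the list alone, with a median log2 change of -2.22. The mitotic kinase gene CDK1 fell from 2583 ± 322 to 363 ± 75.2 (-2.79, SE 0.23), the condensin subunit gene NCAPH from 524 ± 40.1 to 54.1 ± 22.999, and MYBL2 and KIF23 changed by -3.11 and -2.94. Of 52 genes of G1/S and DNA replication, 51 fell and 0 rose, also adjusted over the list alone, with a median of -1.82. GINS1, a part of the replicative helicase, fell from 1189.9 ± 139 to 147 ± 51.8, the ribonucleotide reductase gene RRM2 from 2761 ± 469.9 to 468 ± 119.7, and MCM10 and CDC45 changed by -2.74 and -2.69. limma's camera gave an adjusted p of 2.92e-34 for G2/M and 1.07e-26 for G1/S, and adjusted p = 0.0733 and 0.0605 with an estimated correlation. Both lists also fell in the control course, with mean changes from its 0 h array of -0.90 and -0.75 at 96 h. Between the arms, for 96 h against 0 h, the median differences were -1.23 (35 of 62 lower, 51 adjusted over the list alone) and -1.10 (24 of 52 lower, 38 adjusted over the list alone), with adjusted p = 0.14 for both with an estimated correlation. Cell cycle inhibitors went both ways: 10 of 25 rose and 7 fell (the same counts adjusted over the list alone), with a list median of 0.33 and adjusted p = 0.398. CDKN1A, which encodes p21, rose by 2.36, with signals of 288 ± 232 at 96 h, and GADD45G by 1.91. GAS2L3 and BTG3 changed by -1.87 and -1.26, the latter with probe sets that differed in sign. CDKN1B, which encodes p27, rose by 0.68 (adjusted p = 5.72e-05), from 440.2 ± 9.96 to 717 ± 7.51. The cyclin gene CCND2 stayed at 11.2 ± 8.58 and 8.03 ± 6.25 (adjusted p = 0.719), and CCND1 did not pass the filter, with signals between 0.4 and 15.5 over its 2 probe sets.

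MYC fell from 5022 ± 389 to 3064 ± 177.5 (log2 -0.71, SE 0.11, adjusted p = 4.93e-05), while the control course read 5804 and 6767. Of 35 genes of MYC and ribosome biogenesis, 28 fell and 1 rose (29 and 1 adjusted over the list alone), with a median of -0.70 and a camera adjusted p of 4.85e-09 (adjusted p = 0.0605 with an estimated correlation). CAD, an enzyme of pyrimidine synthesis, changed by -1.41, the ornithine decarboxylase gene ODC1 by -1.29 and the ribosome assembly factor MRTO4 by -1.24. Photoreceptor and visual transduction genes also fell, 26 of 37 against 3 that rose (28 and 4 adjusted over the list alone), with a median of -0.87 and an adjusted p of 2.79e-06 (adjusted p = 0.182 with an estimated correlation). The transducin subunit gene GNGT2 fell from 636 ± 81.8 to 62.2 ± 22.3, the cone phosphodiesterase subunit gene PDE6H from 1332 ± 186 to 220.4 ± 52.0, and ABCA4 and KCNV2 changed by -2.17 and -1.99. CRX, a photoreceptor transcription factor of the OTX family, rose instead, from 143 ± 26.5 to 356 ± 34.5 (log2 1.24, adjusted p = 6.24e-05). The control course went from 124 to 274, and the difference between the arms at 96 h was 0.18 (adjusted p = 0.841). NRL, a rod transcription factor, read 272 ± 122 and 472 ± 153, with a log2 change of 0.81 (adjusted p = 0.0595, 0.00637 with the block, 0.0482 with a pseudocount of 64, 0.0214 without course 2 and up to 0.639 over the alternatives), and its probe sets differed in sign.

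Neuronal differentiation genes rose, 31 of 51 against 6 that fell (33 and 7 adjusted over the list alone), with a median of 0.86 and an adjusted p of 2.76e-07. Among the 8 lists called at 96 h, this 1 kept its call with an estimated correlation (adjusted p = 0.0289). Neural progenitor genes were not called as a list (0.17, adjusted p = 0.0901, and 0.0492 with median centring), although 10 of 29 rose and 6 fell (11 and 6 adjusted over the list alone). INSM1, a zinc finger factor of neurogenesis, rose from 4.37 ± 5.66 to 455 ± 14.1, SOX11 from 4.93 ± 3.74 to 404 ± 36.7, and DLL3 and MYCN rose by 4.16 and 2.36. Of 41 axon guidance genes, 12 rose and 7 fell, as adjusted over the list alone (median 0.23, adjusted p = 0.261), among them CXCR4 (2.65), SEMA5B (2.59) and DPYSL2 (2.07). WNT pathway genes rose as a list, with 9 of 29 higher and 1 lower, also adjusted over the list alone (median 0.33, adjusted p = 0.0446). That call was lost with an estimated correlation (adjusted p = 0.199 with an estimated correlation) and without course 2 (adjusted p = 0.108), and also without the filter (0.0577) and with the mean of probe sets (0.0501). The receptor gene FZD1 rose from 109 ± 31.0 to 763 ± 100.4, GSK3B by 1.25 and AXIN2 by 1.25.

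Of 36 integrated stress response genes, 18 fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.43 and an adjusted p of 0.0016 (adjusted p = 0.327 with an estimated correlation). The amino acid transporter genes SLC7A11 and SLC7A5 changed by -2.43 and -2.02 and the transcription factor CEBPB by -1.87, and DDIT4, an inhibitor of mTOR signalling, rose by 2.20. Cholesterol biosynthesis genes fell, 11 of 20 against 1, also adjusted over the list alone (median -0.45, adjusted p = 0.0021, and adjusted p = 0.199 with an estimated correlation), with SC5D at -1.97 and ACAT2 at -1.34. The other stress and metabolic lists were not called. Hypoxia and glycolysis had 8 higher and 13 lower of 30 (median -0.20, adjusted p = 0.289), and the unfolded protein response 4 and 4 of 22 (median -0.18, adjusted p = 0.692), with the same counts adjusted over the list alone. Of 24 p53 targets, 4 rose and 5 fell (3 and 5 adjusted over the list alone); the median was -0.11, the mean 0.05 and the adjusted p 0.845. TP53INP1 rose by 2.64 and TIGAR changed by -1.15. Of 19 interferon response genes, 6 rose and 5 fell, as adjusted over the list alone, with a median of -0.13, a mean of 0.094 and an adjusted p of 0.981; camera put both of these lists lower.

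Lists of lineage and tumour group markers were not called at 96 h either. The OTX family and anterior hindbrain list had 4 of 11 higher and 0 lower, also adjusted over the list alone (median 0.17, adjusted p = 0.31), with PAX5 at 2.05. Group 3 and group 4 medulloblastoma markers had 3 higher and 1 lower of 7 (4 and 1 adjusted over the list alone; median 0.81, adjusted p = 0.187), with RBM24 at 2.82 and IMPG2 at -0.82. WNT and SHH group markers had 2 higher and 2 lower of 7 (2 and 3 adjusted over the list alone; median -0.01, adjusted p = 0.981), with PDLIM3 at -2.50 and EYA1 at 1.14. Astrocyte and oligodendrocyte markers had 4 higher and 3 lower of 15 (median 0.27, adjusted p = 0.398), with OLIG2 at 1.67 and SLC1A3 at -1.63, and mesenchymal and fibroblast markers 7 and 2 of 17 (median 0.15, adjusted p = 0.0647, 0.0442 without course 3 and 0.0346 with median centring), both with the same counts adjusted over the list alone. SPARC, a matrix glycoprotein, rose from 52.4 ± 11.8 to 1387 ± 248, and COL1A1 by 3.29 on its brightest probe set, while its probe sets differed in sign. None of 7 immune and endothelial markers was called by limma, and 0 were called adjusted over the list alone (median -0.045, mean -0.03, with camera's direction up at an adjusted p of 0.981).

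**Figure D2:**
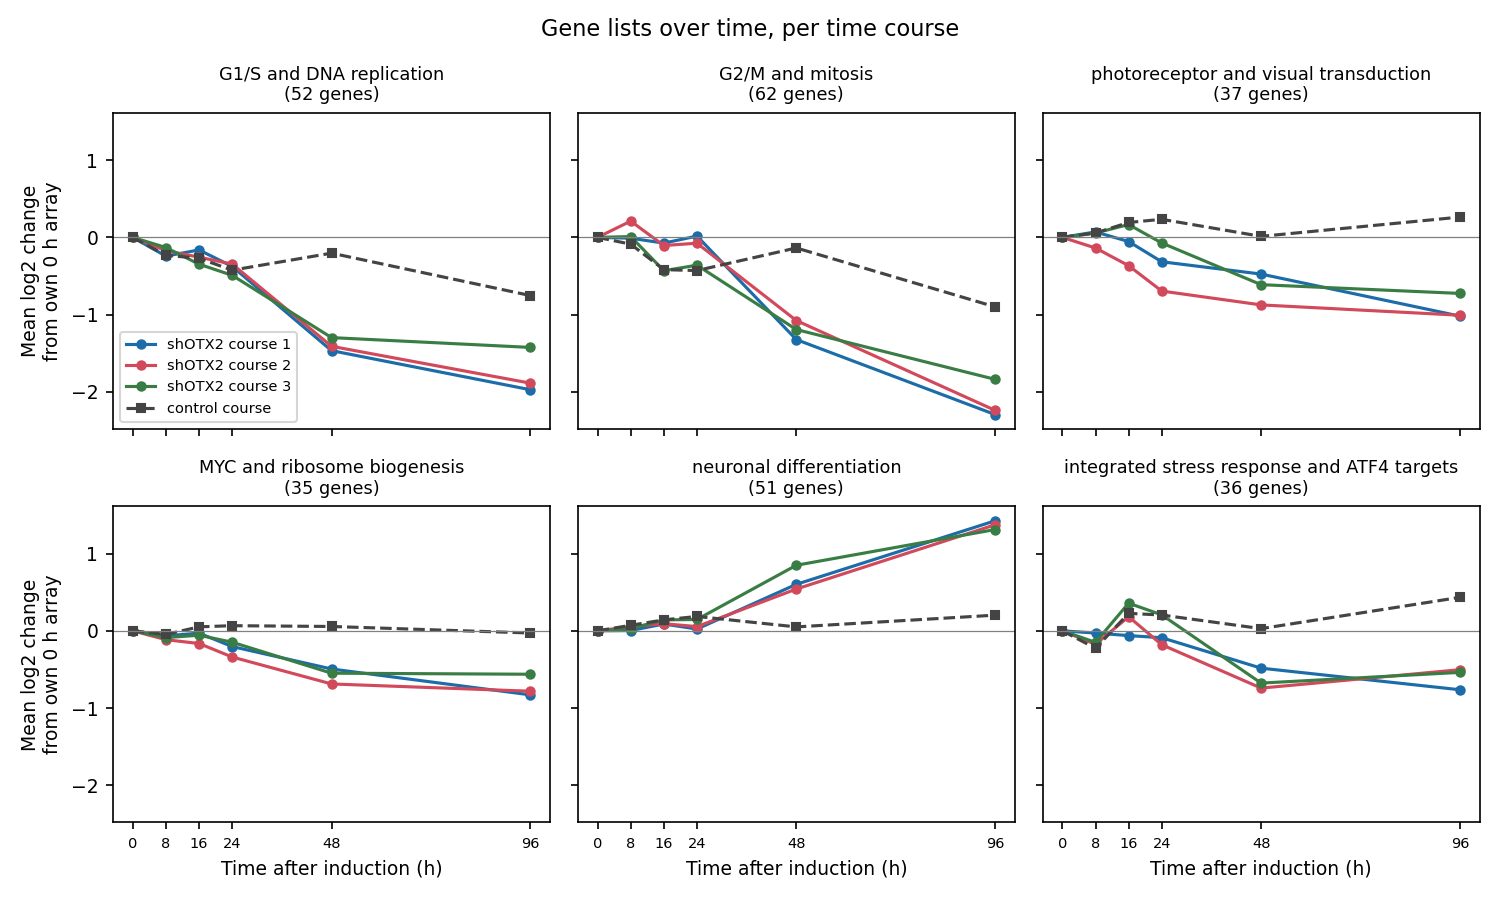
Mean log2 change of 6 gene lists from each course's own 0 h array (vertical axis) against hours after induction, with 1 line per course, solid for the shOTX2 courses and dashed for the control. At 96 h the list medians in the shOTX2 arm are -1.82 for G1/S, -2.22 for G2/M and 0.86 for neuronal differentiation.

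At 8 and 16 h few genes were called. At 16 h USP18, a protease that removes the interferon-induced modifier ISG15, was higher by 2.04 on the log2 scale (SE 0.39, adjusted p = 0.0132), SUSD2 by 1.98 and the glycoprotein hormone gene STC1 by 1.70. The ion channel gene TRPM3 changed by -1.56, the protease gene ADAMTS1 by -1.53 and LGI2 by -1.51. LGI2 also went from 58.7 to 7.30 in the control course. By 24 h USP18 was at 811 ± 287, from 59.3 ± 39.7 at 0 h (3.53), SUSD2 was higher by 2.68, STC1 by 2.54, PPP1R17 by 2.53 and POM121L9P by 2.43. The largest falls at 24 h were those of GULP1 (-2.13), TTC12 (-2.02), ADAMTS1 (-1.92), SLCO4A1 (-1.83) and TRPM3 (-1.79).

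limma called 0 genes at 8 h against 0 h, with 462 at an unadjusted p under 0.05 where chance gives 695, and 0 with the block. It called 142 genes at 16 h (88 higher, 54 lower) and 853 at 24 h (480 higher, 373 lower), and 794 and 2128 with the block. These early counts varied with the arrays used. Without course 2 the call is lost for all 6 named genes at 16 h and for POM121L9P, ADAMTS1 and SLCO4A1 at 24 h. There were then 0 genes called at 16 h and 87 at 24 h. Without course 3 there were 38 and 321, and SUSD2 and TRPM3 lost their 16 h calls (adjusted p = 0.178 and 0.0792). Without course 1, USP18, SUSD2 and ADAMTS1 lost theirs at 16 h (adjusted p = 0.081, 0.0772 and 0.0648). With only the groups compared in the fit there were 0 and 360. The fits without a course had no block and 6 residual degrees of freedom in place of 12. Their median residual SD was 0.178 without course 1, 0.237 without course 2 and 0.235 without course 3. The spread was nearly the same without course 2 and without course 3, so these early counts leaned more on course 2. The named 16 h changes without course 2 were 1.64 (USP18), 1.66 (SUSD2), 1.43 (STC1), -1.47 (TRPM3), -1.46 (ADAMTS1) and -1.62 (LGI2). The losses therefore do not show that the early changes came from course 2 alone.

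As lists, camera called 2 at 8 h and 5 at 16 h (4 and 7 with the block), while fry called 0 at either time. At 8 h G1/S genes had a median of -0.15 (adjusted p = 1.05e-08) and MYC and ribosome biogenesis of -0.054 (adjusted p = 0.0306), with 0 members of either called, also adjusted over the list alone. At 16 h G1/S (-0.25; 1 lower, 2 adjusted over the list alone) and G2/M (-0.21; 0 called, also adjusted over the list alone) were lower. Neural progenitor (0.21; 1 higher, 2 adjusted over the list alone), unfolded protein response (0.17; 0 called, 2 higher adjusted over the list alone) and integrated stress response genes (0.11, adjusted p = 0.0109; 0 called, also adjusted over the list alone) were higher, the last opposite to their direction at 96 h. None of these kept its call, with adjusted p = 0.801 for both lists at 8 h and from 0.374 to 0.555 at 16 h with an estimated correlation. In the control course the mean change of G1/S genes from its own 0 h array was -0.23 at 8 h and -0.27 at 16 h, and at 16 h that of G2/M was -0.42 and that of the integrated stress response 0.23. That of MYC and ribosome biogenesis was -0.047 at 8 h, and at 16 h that of neural progenitor genes was 0.13 (shOTX2 courses 0.19, 0.30 and 0.10) and that of the unfolded protein response 0.10 (0.13, 0.36 and 0.16).

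At 24 h, 7 lists were called (8 with the block). G1/S genes had a median of -0.39 (7 of 52 lower, 17 adjusted over the list alone, camera adjusted p = 3.49e-14) and photoreceptor genes a median of -0.34 (7 lower and 1 higher, 12 and 1 adjusted over the list alone, adjusted p = 1.17e-04). MYC and ribosome biogenesis (-0.25), cholesterol biosynthesis (-0.27) and G2/M (-0.11) were lower as lists, each with 1 member lower, and 1, 4 and 1 adjusted over the list alone. Neural progenitor genes (0.22; 4 higher and 1 lower, 7 and 1 adjusted over the list alone) and unfolded protein response genes (0.21; 2 higher, 7 adjusted over the list alone) were higher as lists. None of the 7 kept its call with an estimated correlation, where the adjusted p ran from 0.209 to 0.909. The control course also moved in 4 of them: its mean change from 0 h was -0.42 for G1/S (shOTX2 courses -0.38, -0.35 and -0.49), -0.43 for G2/M (0.017, -0.075 and -0.36), 0.22 for the unfolded protein response (0.22, 0.33 and 0.23) and -0.21 for cholesterol biosynthesis (-0.14, -0.31 and -0.26). It was 0.23 for photoreceptor genes, where the shOTX2 courses had -0.32, -0.69 and -0.073. For MYC and ribosome biogenesis it was 0.066 (-0.20, -0.34 and -0.15), and for neural progenitor genes 0.069 (0.37, 0.32 and 0.19). The difference between the arms at 24 h was not tested.

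At 48 h limma called 4625 genes, 2256 higher and 2369 lower. The lists called at 48 h were 9 (10 with the block, which adds the unfolded protein response, median 0.19, adjusted p = 0.0878 without it and 0.0289 with it), among them G1/S (-1.46, 49 of 52 lower, 50 adjusted over the list alone), G2/M (-1.22, 58 of 62 lower, 58 adjusted over the list alone) and neuronal differentiation (0.48, 21 higher and 6 lower, 23 and 6 adjusted over the list alone). None of the 9 kept its call: with an estimated correlation these had adjusted p = 0.0978, 0.11 and 0.104, and the other 6 from 0.0978 to 0.197. Genes called the same way at 48 h and 96 h numbered 3989 (1861 higher, 2128 lower), and 9 were called in opposite directions. Independent lists of these sizes would share 1008. At an unadjusted p under 0.05 in limma both times shared 4800, against a median of 43.5 (highest 57) in 20 simulations with no effect and shared 0 h arrays. With no effect chance gives 695 genes at each time, against 5775 at 48 h and 6882 at 96 h here. The simulations therefore cannot show how much overlap the shared arrays add to lists of this size. Both times share the 3 arrays at 0 h, too few to divide, so part of the excess over 1008 may come from them. Without course 2 there were 2668 genes at 48 h and 2378 at both times, and 2992 and 2591 without course 3.

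**Figure D3:**
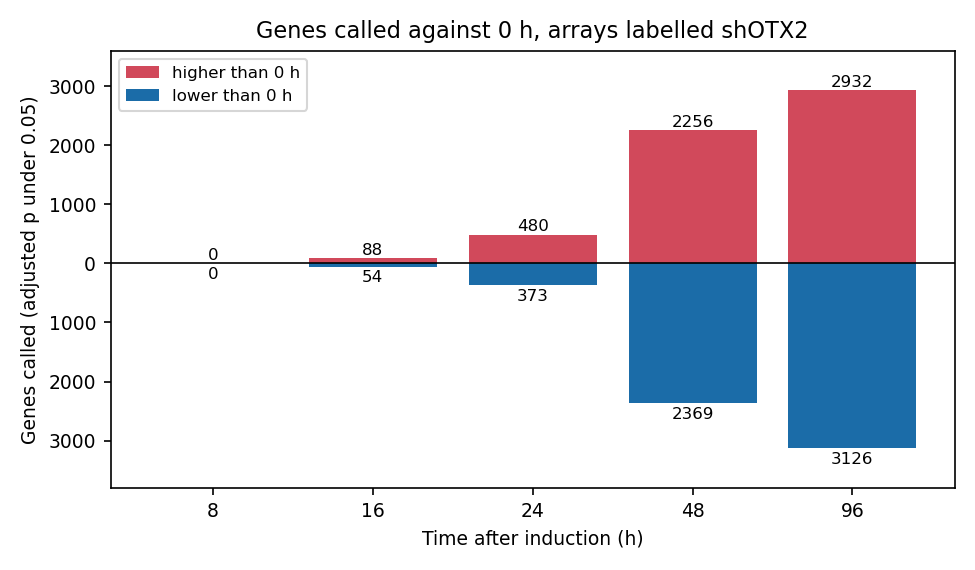
Number of genes called against 0 h (adjusted p under 0.05, vertical axis) in the arrays labelled shOTX2 at each time after induction in hours (horizontal axis). Bars above 0 are genes higher and bars below 0 genes lower than at 0 h, from 0 at 8 h to 2932 and 3126 at 96 h.

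The control course asks what time in culture and doxycycline do without the hairpin. Late arrays (48 and 96 h) were set against early ones (0 and 8 h) in each arm, and the change in the control was taken from that in shOTX2. PPP1R17 rose more in shOTX2 by 5.07 (SE 0.46, adjusted p = 9.57e-07), CNTN2 by 4.90, SSTR2 by 4.69, SLC7A7 by 4.68, MFAP4 by 4.64 and FNDC5 by 4.61. TIMP3 differed by -3.92 (SE 0.40, adjusted p = 2.90e-06), SLC60A1 by -3.85, ERC2 by -3.77, the hexokinase family gene HKDC1 by -3.64, CA2 by -3.58 and GNGT2 by -3.33. In the control course these 12 genes had late minus early changes between -0.29 and 0.84.

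**Figure D4:**
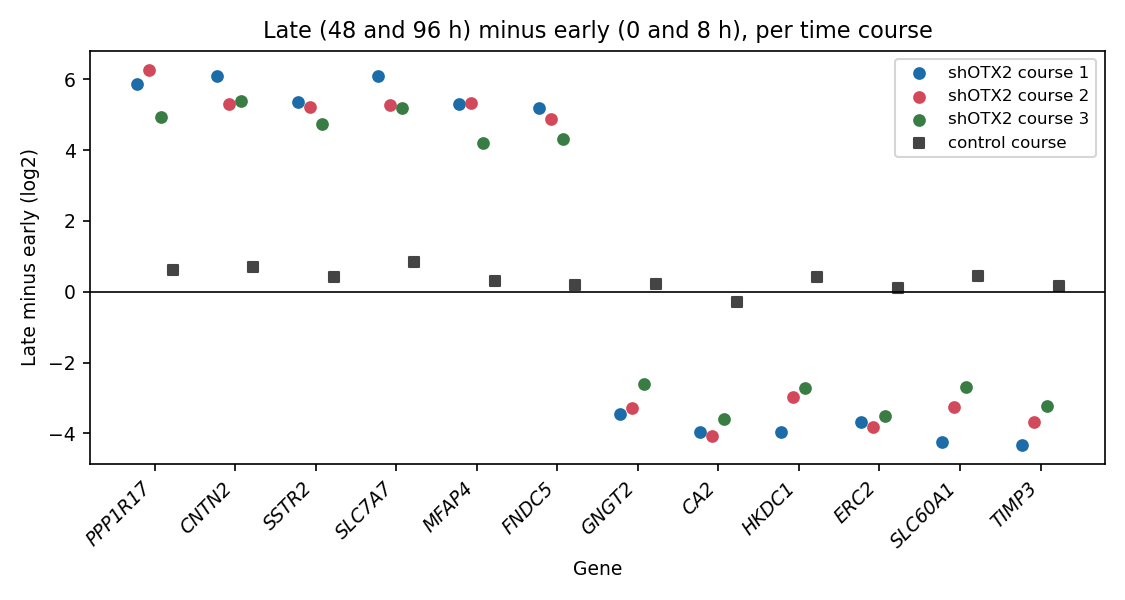
Late (48 and 96 h) minus early (0 and 8 h) change in log2 signal (vertical axis) of the 12 genes with the largest differences between the arms (horizontal axis), circles for each shOTX2 course and squares for the control. For every gene shown the shOTX2 courses lie on 1 side of the control, with differences from -3.92 for TIMP3 to 5.07 for PPP1R17. The genes were chosen by this difference, so lying on 1 side largely follows from the choice.

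For the difference between the arms 9 lists were called, given here with their medians. Genes of G2/M (-1.30; 55 of 62 lower, 59 adjusted over the list alone) and G1/S (-1.20; 44 of 52 lower, 45 adjusted over the list alone) fell more in shOTX2, with camera adjusted p = 1.56e-25 and 1.19e-21. So did photoreceptor genes (-0.84; 18 lower and 2 higher, 19 and 2 adjusted over the list alone), MYC and ribosome biogenesis (-0.68; 19 lower, 25 adjusted over the list alone), the integrated stress response (-0.66; 19 lower and 1 higher, 25 and 1 adjusted over the list alone) and cholesterol biosynthesis (-0.45; 8 lower and 1 higher, the same adjusted over the list alone). Neuronal differentiation genes rose more in shOTX2 (0.62; 23 higher and 4 lower, 24 and 4 adjusted over the list alone), as did neural progenitor (0.26; 10 and 3, 11 and 3 adjusted over the list alone) and mesenchymal markers (0.39; 6 and 1, 7 and 1 adjusted over the list alone). With an estimated correlation none of the 9 was called: adjusted p = 0.0724 for MYC and ribosome biogenesis and for neuronal differentiation, 0.0922 for both cell cycle lists, photoreceptor, neural progenitor and integrated stress response genes, 0.234 for cholesterol biosynthesis and 0.214 for mesenchymal markers. The neural progenitor and mesenchymal calls were also lost without the control array at 96 h (adjusted p = 0.0746 and 0.0591), and the cholesterol call on probe sets without _s, _x or _a (0.0616). For 96 h against 0 h between the arms 9 lists were called, among them neuronal differentiation (1.11; 22 higher and 4 lower, 24 and 6 adjusted over the list alone), which kept its call (adjusted p = 0.0442 with an estimated correlation), while the other 8 did not (0.0964 to 0.313). The unfolded protein response was among these 8 (-0.57; 5 lower, 7 lower and 1 higher adjusted over the list alone, adjusted p = 0.00286) although not called late against early (adjusted p = 0.452), and mesenchymal markers were not called (adjusted p = 0.0515). The 96 h difference of the unfolded protein response rests on 1 control array at each time. Without the control array at 48 h that list was also called late against early, with a median of -0.30. Late against early, median, mean and test differed in sign for the uncalled OTX family (-0.041, mean 0.10, camera up), WNT and SHH group (0.044, mean -0.081, camera up) and p53 lists (-0.066, mean 0.034, camera down).

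Genes whose late against early change differed between the arms numbered 3119 (1452 higher and 1667 lower in shOTX2), and 4862 with the block. Median centring shifted the median of all genes by -0.12 and gave 1109 higher and 2143 lower. With course 1 alone, whose actin ratio is close to that of the control, the count was 3496, a setting added after the data were seen. It sets single arrays against each other with the spread of courses 2 and 3 alone (median residual SD 0.178, against 0.233 over all 3 courses). Within the shOTX2 arm 6840 genes were called late against early (3432 higher, 3408 lower), and 3019 of these were also called with the same sign against the control. For 96 h against 0 h, the arms differed in 1896 genes (863 higher, 1033 lower), and in 3598 with the block. The control groups hold 1 array each and are assumed to vary like the shOTX2 groups. Without course 2 the late against early count was 1893 and the 96 h count 869, and without the control array at 48 h the former was 2061.

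In the control course itself, late against early, G2/M genes had a median of -0.49 and G1/S genes of -0.36, while integrated stress response genes had a median of 0.37 and unfolded protein response genes of 0.17. camera called these 4 lists, with adjusted p = 3.54e-26, 1.40e-15, 3.98e-07 and 0.0188, and adjusted p = 0.212, 0.212, 0.212 and 0.434 with an estimated correlation. Single genes were not called: limma gave 0, with 1108 at an unadjusted p under 0.05, and 88 with the block (32 higher, 56 lower). Adjusted over the list alone, 11 G2/M and 5 G1/S genes were lower and 0 genes of the other 2 lists were called. A fit of the control arrays alone also called 0, with 616 at an unadjusted p under 0.05. Counts of 8 without the control array at 48 h, 19 without the control array at 96 h and 6 without course 1 were also obtained.

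Before induction the shOTX2 arrays already differed from the single control array in some genes. At 0 h COL11A1, a fibrillar collagen gene, read 369.7 ± 15.3 in shOTX2 and 1.40 in the control (log2 4.47, SE 0.35, adjusted p = 3.98e-06), and fell to 65.4 ± 28.5 by 96 h. COLEC12 (2.32), LIN7A (2.30) and RNF182 (2.25) were also higher in shOTX2. ZNF22, a zinc finger gene, read 4.57 ± 6.87 against 215 (-3.54), and MAGEB1 (-2.04), MAGEA11 (-1.95) and the histamine receptor gene HRH1 (-1.84) were lower. Integrated stress response genes had a median of -0.56 and photoreceptor genes of 0.31 (camera adjusted p = 2.47e-09 and 8.79e-04, and adjusted p = 0.385 and 0.926 with an estimated correlation). Of single members, 0 integrated stress response genes and 2 photoreceptor genes were called adjusted over the list alone and 0 of either over all genes by limma, which gave 1291 of all genes at an unadjusted p under 0.05.

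limma called 63 genes at 0 h (46 higher and 17 lower in shOTX2). The count was 637 without course 1, 16 without course 2 and 23 without course 3, with a median residual SD of 0.178, 0.237 and 0.235. The 637 rest on courses 2 and 3, which differ from the control in actin ratio (2.07 and 1.91 against 1.40) and on the second component. Course 1 alone gave 173, from 1 array against 1 with the spread of courses 2 and 3. The count thus depends on which courses are set against the single control array, and the call of COLEC12 was lost without course 2 and that of MAGEA11 without course 3.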

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

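The tests on the integrated stress response list and the setting with course 1 alone were chosen only after the result was seen. The arms differed in their change over time, by a test of the difference itself. limma called 3119 genes late against early and 1896 genes for 96 h against 0 h. The 12 genes singled out were PPP1R17 (5.07), CNTN2 (4.90), SSTR2 (4.69), SLC7A7 (4.68), MFAP4 (4.64), FNDC5 (4.61), TIMP3 (-3.92), SLC60A1 (-3.85), ERC2 (-3.77), HKDC1 (-3.64), CA2 (-3.58) and GNGT2 (-3.33), as log2 differences between the arms. The lists that differed were, by their median, photoreceptor and visual transduction (-0.84), G1/S (-1.20), G2/M (-1.30), MYC and ribosome biogenesis (-0.68), neuronal differentiation (0.62), neural progenitor (0.26), integrated stress response (-0.66), cholesterol biosynthesis (-0.45) and mesenchymal markers (0.39). None of these 9 lists was called with another correlation between genes, adjusted p = 0.0724 to 0.234 with an estimated correlation. The late against early count was 1893 without course 2 and 2061 without the control array at 48 h, and the 96 h count 869 without course 2. The neural progenitor and mesenchymal calls were lost without the control array at 96 h (adjusted p = 0.0746 and 0.0591).

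Control probes outside the tested genes gave an actin 3'/5' ratio of 2.07 in course 2 and 1.91 in course 3, above the 1.40 of the control arrays. With course 1 alone, at 1.42, as the shOTX2 arm, the late against early count was 3496 and the 96 h count 2563. These counts set single arrays against each other and take their spread from courses 2 and 3 alone (median residual SD 0.178, against 0.233 over all 3 courses), so they do not exclude that RNA or labelling quality adds to the difference between the arms.

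The integrated stress response list moved in opposite directions in the arms: its late minus early median was -0.45, -0.43 and -0.42 in courses 1 to 3 and 0.37 in the control. Under the other scalings the median difference between the arms lay between -0.77 and -0.63 and stayed called with a highest adjusted p of 2.53e-07 (adjusted p = 0.0922 with an estimated correlation), which argues against the scaling as the cause. Without any 1 of the 4 control arrays it was between -0.86 and -0.61 and called (highest adjusted p = 1.83e-04), which argues against a single control array. Both tests read only the difference between the arms, so they weigh scaling and single arrays as causes of that difference alone. A fall in shOTX2 by itself could keep the difference, and the control's own rise was not weighed. The state of the single control course stays open, since the list already stood -0.56 apart at 0 h and there is 1 control course, so this may be a property of that culture.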

How the results depend on the processing

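The second OTX2 probe set and course 1 alone as the shOTX2 arm were tests chosen only after the result was seen. Of 243 alternatives for 15 main results, 208 left the direction, the side of the threshold or the count within 1.5 times, and the cause of the other changes was not tested unless given here. Among named genes, 2104 of 2157 alternatives changed nothing, 45 ended a call, 3 made one and 5 reversed a sign, and 117 of 137 called values kept their call throughout. Among the lists, 774 of 817 changed nothing, 22 ended a call and 21 made one. For the change at 96 h, OTX2 was called under median centring (-0.30, adjusted p = 0.00977) and with the replicate block (-0.15, adjusted p = 0.0331), with adjusted p from 0.00977 to 0.898 over its alternatives, and the second probe set gave 0.12. The replicate block gave 794 genes at 16 h, 2128 at 24 h, 88 in the control late against early, and 4862 and 3598 between the arms (late against early, and 96 h), where taking out the course offsets lowers the median residual SD from 0.233 to 0.176. It was not run for the arms at 0 h, which cannot be compared with the control course as its own block. For the other values of named genes it changed 1 call, that of NRL, and for lists at 96 h and late against early between the arms 0 of 42; the stricter filter was run for 40 of these. With only the groups compared there were 0 genes at 16 h and 360 at 24 h, with 4 residual degrees of freedom in place of 12. The control called 1 gene with a pseudocount of 1 and 1 with 64, and a pseudocount of 1 gave 99 at 0 h. Course 1 alone, as single arrays with the spread of courses 2 and 3, gave 173 at 0 h. An estimated correlation left 1 list at 96 h and 0 late against early between the arms, while fry, which does not compare a list with other genes, gave 16 and 15. Median centring moved the share of higher calls at 48 h from 48.8% to 36.0%, late against early in shOTX2 from 50.2% to 36.8%, and between the arms from 46.6% to 34.1% (late against early) and from 45.5% to 35.5% (96 h), with shifts of -0.12, -0.13, -0.12 and -0.11 in the median of all genes. It also made calls of neural progenitor (median 0.024) and mesenchymal markers (median -0.0019, camera up) at 96 h.

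Leaving out 1 course or control array gave ranges of 0 to 99 genes at 16 h, 87 to 778 at 24 h, 2668 to 4851 at 48 h, 2378 to 4115 at both 48 and 96 h, 0 to 19 in the control, 1893 to 4043 and 869 to 2641 between the arms and 16 to 637 at 0 h. At 96 h the range was 4197 to 6155, and late against early in shOTX2 it was 5133 to 6958. The lowest of each came without course 2, except in the control, where 8 came without the array at 48 h, 19 without that at 96 h and 6 without course 1. Each fit without a course has 6 residual degrees of freedom in place of 12, so the degrees of freedom do not set those counts apart. Without course 1 the median residual SD was 0.178, against 0.237 without course 2 and 0.235 without course 3, and 637 genes at 0 h, 4851 at 48 h and 6155 at 96 h were called. Of the 6058 genes at 96 h, 4126 kept their call without course 2 and 5369 under median centring. Uncalled values that changed sign were those of CCND2, from -0.59 to 0.082 over the left-out courses (0.024 without course 1, 0.082 without course 3), CD74 (0.14 without the filter) and NRL (-0.33 on its probe set without _s, _x or _a). PDGFRA, called higher at 96 h, was -0.23 without the filter, which takes another probe set. Dim genes limit all of this, since no detection calls were used, and a gene near the array median of 16.3 to 20.6 has a change compressed by the pseudocount.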

Other observations

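The tests on the muscle list and on the OTX2 signal were chosen only after the result was seen, and the counts of other splits were planned. Among the largest rises at 96 h were NEB and ITGA7, which encode a thin filament protein and a laminin receptor of skeletal muscle, and a list of 58 skeletal muscle genes was then written and tested. Of its 56 genes with a probe set, 33 were tested, 16 rose and 3 fell. NEB rose by 5.54 on the log2 scale, ITGA7 by 5.49, the calcium pump gene ATP2A1 by 4.70, LDB3 by 4.39, the acetylcholine receptor gene CHRNA1 by 4.11, the troponin gene TNNC2 by 3.81 and the myogenic factor gene MYOG by 1.72. MYL4, CASQ1 and JPH1 changed by -2.06, -2.31 and -2.12. The list's median was 0.55, with a camera p of 2.03e-04 and a p of 0.00131 with an estimated correlation, on genes picked after 2 of them had been seen to rise. In each shOTX2 array at 0 h, 9 of the 33 lay above the array median, and 0 of the 33 were in a list fixed before. The sign of the change was the same in all 3 courses for the 16 risen genes, which were chosen by the mean of those courses.

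Members of the interferon list went apart. USP18 rose from 59.3 ± 39.7 (SD, n = 3) to 1171 ± 277 and IFI44L from 3.20 ± 4.25 to 398 ± 72.5, while IFITM3, a membrane protein that restricts virus entry, fell from 187 ± 43.0 to 12.3 ± 4.43 and IFITM2 from 206 ± 72.6 to 25.1 ± 28.8. Against the control the late minus early differences were 4.43, 3.96, -1.13 and -1.75, each called by limma (adjusted p = 2.06e-05, 8.85e-07, 0.0352 and 0.0311).

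For the 16 risen muscle genes the median late against early difference between the arms was 1.55, with 12 called, and the control's own median was 0.36. These genes were chosen by their rise in the same shOTX2 arrays, so that difference was partly fixed in advance. Another choice was made from the same 33 tested muscle genes, so it can overlap the 16. It took 12 genes by their rise in the fit without course 1, with NEB and ITGA7 left out. Their median late minus early change was 1.85 in course 1 and 0.38 in the single control course. This argues against time in culture or doxycycline alone for these 12 genes. The batch of arrays, as far as the actin ratio marks it, was weighed on the same 12 genes. It is argued against by their median late minus early change of 1.43 for course 1 minus the control, whose mean actin ratios were 1.42 and 1.40, with all 12 higher in course 1. Of 17 other transcripts taken as abundant in muscle, 7 were tested and 0 were called by limma at 96 h (0 at an unadjusted p under 0.05), with a median signal of all 17 of 7.10 (highest 176, TTN), or 4.27% of the 166 of the risen genes. The rest did not pass the filter, signals of different probe sets are not on 1 scale, and NEB, TNNC2, ATP2A1 and TNNI1, which rose, are abundant in muscle too. Admixed muscle cells therefore stay open beside a change in the tumour cells.

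The OTX2 signal stayed near its 0 h level while 6058 other genes were called at 96 h. A signal ceiling common to all probe sets is argued against, since of 100 genes at least as bright at 0 h 30 were called lower. Of these, 2 fell at least 2-fold (KPNA2 and ODC1, the latter by -1.29). Signals of different probe sets are not on 1 scale, so this does not weigh a ceiling of the OTX2 probe sets alone. Partial compression stays open too. The lowest OTX2 signal of any array was 77.2% of its arm's 0 h mean, so these probe sets show no array with clear silencing under any label. With no such array, these probe sets cannot tell whether arms or times were mislabelled. The first principal component lay between 38.2 and 71.3 in the shOTX2 arrays at 48 and 96 h. It lay between -26.8 and -12.7 in the control arrays and reached at most -3.17 in earlier shOTX2 arrays. These values argue against an exchange of late shOTX2 arrays with those. The probe sets themselves do not check the labels, and an exchange of whole arms stays open. That the probe sets may read a part of the transcript that silencing leaves, or that protein fell more than RNA, stays open: the change of -0.15 decides neither, and the place of the hairpin target was not given.

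Chance was weighed by splitting the same arrays in other ways. For 96 h against 0 h, 1 of 10 splits gave as many genes (6058, highest other 0), and the same held at 48 h (4625, highest other 0), 24 h (853, highest other 0) and 16 h (142, highest other 0), while at 8 h all 10 splits did (0, with 462 at an unadjusted p under 0.05, highest other 1). With 10 splits the share cannot fall under 0.05. For lists at 96 h, 3 of 10 splits gave as many (8, highest other 9), and among the 4 splits that part all 3 pairs of courses the highest other was also 8. For shOTX2 late against early, 1 of 100 drawn splits of the 12 arrays gave as many genes (6351, highest other 3209). These counts come from a fit of the 12 arrays as 2 groups, and the share is under 0.05 over the splits drawn. Most of the splits spread the courses unevenly over the 2 sides, so course offsets enter their spread. Of these, 21 had the same number of arrays from each course on both sides, the real one included, and the highest other of them had 0. The split with 3209 had 5 of the 6 late arrays on 1 side, and splits with 3 or 4 gave at most 1. For genes called at both 48 h and 96 h, 1 of 100 drawn splits of the 9 arrays gave as many (3772, highest other 26). Most of these splits spread the courses unevenly over the times, so course offsets enter their spread. The 18 of them with 1 array of each course at each time, the real one included, had a highest other of 26. They are too few for a share under 0.05, so chance is not excluded among splits that keep the pairing.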
